A study of Mus musculus with 6 samples.

How the data were processed

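ChIP-seq was done in J1 mouse embryonic stem cells carrying BirA. Per the labels, chromatin was cross-linked with formaldehyde and libraries were made with a commercial kit for ChIP DNA and sequenced on Illumina instruments. The series held 6 samples, of which 5 had a peak list used here, for Tgif1, Tgif2, Hdac1, Nanog and Smad3. Each factor formed its own group of 1 library, so each list came from a single library and nothing could be compared between replicates. The mock library from BirA cells was not analysed here. The submitters' processing notes name BWA 0.5.9-r16, MACS and the mm9 build, with no settings and no version of MACS. Which control library each list was called against is not given in the sources used here, and neither is the threshold of the peak calls or the depth of the libraries.

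The deposited lists have no header, so their columns were identified from the values. The first columns are chromosome, start and end. The deposited lists carry a fold enrichment per peak, a ratio of the peak to its background as the authors' peak caller gave it. This was read from values with 2 decimals and no negatives. The deposited lists also carry a whole number per peak, read as the count of tags in the peak. It followed peak width more closely than fold, with rank correlations across peaks of 0.64 to 0.81 with width and of -0.04 to 0.55 with fold, and each list had its own minimum. No column was read as a p-value or a false discovery rate. The last 3 columns were equal in all 70533 peaks and lay inside the peak, and were taken as the summit. Whether starts count from 0 or from 1 is not stated, so coordinates are printed as deposited and carry an uncertainty of 1 bp. Fold and tags are the authors' values and were used only to describe and rank peaks within a list. No peaks of the same list overlapped each other.

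Peaks were called shared when they overlapped by at least 1 bp. Shares were counted over the peaks of the named list and given with 95% Wilson intervals. Chance came from 1000 circular rotations of the other list within each chromosome, over the range that the 5 lists together cover there. A one-sided permutation p was the share of rotations with at least the observed overlap, with the observed lists counted in, adjusted by Benjamini-Hochberg over the 20 ordered pairs. Regions by combination were unions of overlapping peaks, with chance from rotating every list. Occupancy of Nanog peaks by Tgif1 or Tgif2 was split by Hdac1 and described by conditional odds ratios with exact 95% intervals. Summit distances were taken from each Tgif1 summit to the nearest summit of the other factor among overlapped peaks. Their chance came from 1000 random placements of the Tgif1 summit inside its peak, and their intervals from order statistics.

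The comparisons and alternatives were fixed before the data were examined, unless stated otherwise. The planned ranking by a p-value score could not be made, so fold enrichment, the next measure named in the plan, ranked the peaks, and tag number was the alternative. This choice was made after the strongest peaks under both rankings had been seen. The named regions followed a rule fixed beforehand for the case without annotation. It took the 10 strongest Tgif1 peaks, the 3 strongest of each other list and the 5 places with all factors that had the highest Tgif1 fold. The overlap of Nanog and Hdac1 peaks by bins of strength and the summit distances between other pairs were added after the data were seen. The odds ratios within bins of Nanog fold had been fixed beforehand.

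The alternatives fixed beforehand were the peaks at or above each list's median fold, an overlap of at least 50% of the shorter peak, summits within 200 bp, peaks set to 250 bp each side of the summit, autosomes only, uniform placement, lists of equal length, merging within 500 bp and leaving out the Smad3 list. Moves of 10 to 50 kb, leaving out chromosome 1 and leaving out the 1% of peaks with the most tags were added after the data were seen. Promoter shares, genes near peaks, gene lists and motifs were planned but not run, because annotation and sequence of the mm9 build were not used here. Regions are given by coordinates without gene names.

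The overlap counts were tested on simulated data in which 20% or 60% of the 16400 Tgif1 peaks were copied into another list. The expected overlaps were 21.1% and 60.3%, and 21.4% and 60.6% were recovered. Counts on the real lists were also checked against bedtools 2.31.1, and 0 of 40 differed. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.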

Results

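Binding sites of 5 proteins were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in J1 mouse embryonic stem cells grown with leukemia inhibitory factor. The cells carried BirA, a bacterial enzyme that attaches biotin to tagged proteins. Tgif1 is a homeodomain corepressor that binds Smad proteins and recruits histone deacetylases, and Tgif2 is its paralog. Hdac1 is a histone deacetylase of several corepressor complexes, Nanog is a homeodomain factor of the pluripotency network, and Smad3 carries TGF-beta and Activin signals to chromatin. Per the labels, Tgif1, Hdac1 and Smad3 were precipitated with antibodies, and Nanog and Tgif2 with streptavidin beads. The series design names the biotin method for Nanog but does not mention it for Tgif2. Each factor had 1 library and 1 peak list. The mock library from BirA cells was not analysed here, so no background level from a control stands beside the values. With 1 library per factor no value had a replicate check. The 95% intervals are Wilson intervals over peaks and cover counting error only, and peaks are not biological replicates.

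The Tgif2 list was the longest with 19129 peaks, followed by Nanog with 17272, Hdac1 with 16506 and Tgif1 with 16400, whereas Smad3 had 1226. Peaks covered 20.2 Mb for Tgif2, 17.1 Mb for Tgif1 and 0.890 Mb for Smad3. The median peak was 1038 bp wide for Hdac1, 943 bp for Tgif2, 933 bp for Tgif1, 689 bp for Smad3 and 633 bp for Nanog. The tags inside peaks summed to 1347497 for Tgif2, 1091641 for Tgif1, 904246 for Hdac1, 821817 for Nanog and 43227 for Smad3. The median peak held 57 tags for Tgif2, 54 for Tgif1, 47 for Hdac1, 30 for Nanog and 26 for Smad3. The smallest number of tags in a peak was 33 for Tgif2, 30 for Tgif1, 28 for Hdac1, 16 for Nanog and 11 for Smad3. Sequencing depth of the whole libraries is not given in the sources used here, so the list sizes cannot be set against it.

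The comparisons asked where Tgif1 bound relative to its paralog, to Hdac1, to Nanog and to Smad3. In the full lists, most Tgif1 peaks coincided with peaks of Tgif2 and of Hdac1. A Tgif2 peak overlapped 12992 of the 16400 Tgif1 peaks, which was 79.2% (95% interval 78.6 to 79.8). Hdac1 peaks overlapped 10843 Tgif1 peaks, or 66.1% (65.4 to 66.8), and Nanog peaks overlapped 6015, or 36.7% (35.9 to 37.4). The shorter Smad3 list overlapped 826 Tgif1 peaks, or 5.04% (4.71 to 5.38). After rotation of the other list around each chromosome, the mean overlap was 1.74% for Tgif2, 1.58% for Hdac1, 1.22% for Nanog and 0.0908% for Smad3. The observed shares were therefore 45.6, 41.9, 30.0 and 55.5 times the chance level. Against moves of each peak by only 10 to 50 kb, a comparison chosen after the data were seen, they were 13.4, 12.3, 9.98 and 14.6 times chance. Each had a one-sided permutation p = 0.001, the smallest the 1000 rotations can give, and an adjusted permutation p = 0.001 over the 20 ordered pairs of lists. With peaks at or above each list's median fold, which also leaves fewer peaks to overlap, the share was 65.5% for Tgif2 and 47.7% for Hdac1. By summits within 200 bp it was 62.6% and 48.7%, so a majority with Hdac1 depended on the setting. Whether the Tgif1 antibody also binds Tgif2 was not tested here.

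The order of the shares held on most chromosomes. Tgif2 overlapped a larger share of Tgif1 peaks than Hdac1 on 20 of 20 chromosomes, and Nanog a larger share than Smad3 on 20 of 20. The Smad3 list held only 23 peaks on the X to 97 on chromosome 11, against 110 and 1501 for Tgif1. List length therefore largely set the order of Nanog over Smad3 in advance. Hdac1 exceeded Nanog on 19 of 20, the exception being the X chromosome with 29.1% for Hdac1 and 33.6% for Nanog among 110 Tgif1 peaks. The share of Tgif1 peaks with Tgif2 ranged from 58.2% on the X to 86.9% on chromosome 1, and the share with Nanog from 30.0% on chromosome 7 to 48.4% on chromosome 1. The median Tgif1 peak held 62 tags on chromosome 1 and 54 on the other autosomes. Chromosome 1 also held 8.31% of Tgif2 and 9.33% of Nanog peaks, against 7.07% of Tgif1 and 7.05% of Hdac1 peaks. Neither tags nor the number of peaks was tested as a source of the chromosome 1 shares.

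**Figure D1:**
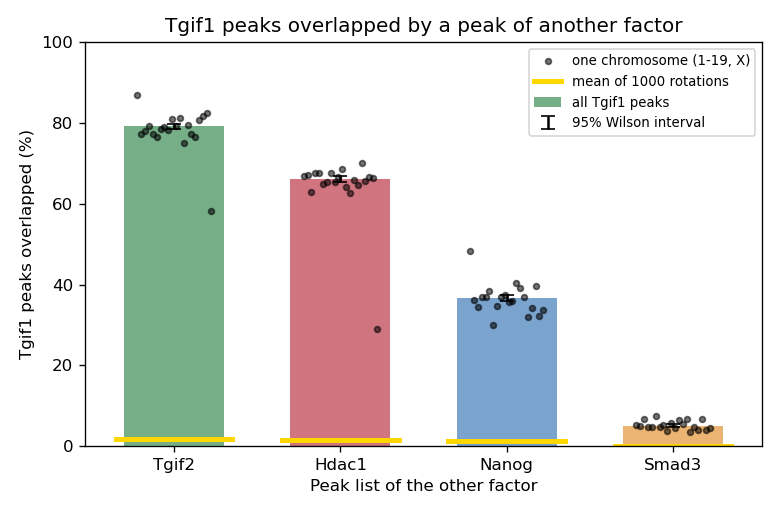
Share of the 16400 Tgif1 peaks (vertical axis, %) overlapped by at least 1 bp by a peak of Tgif2, Hdac1, Nanog or Smad3 (bars, with 95% Wilson intervals), with the share on each of 20 chromosomes (dots) and the mean of 1000 rotations (yellow lines). The bars fall from 79.2% for Tgif2 to 5.04% for Smad3, and the chance levels lie at or below 1.74%.

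Because a long list overlaps more peaks than a short one, the lists were also compared at equal length, where Tgif2 remained first. With each list limited to the 1226 peaks with the highest fold enrichment, the length of the Smad3 list, Tgif2 overlapped 48.9% of Tgif1 peaks (46.1 to 51.7). Hdac1 overlapped 21.5% (19.3 to 23.9), Nanog 7.01% (5.72 to 8.58) and Smad3 6.36% (5.13 to 7.87). The intervals of Nanog and Smad3 overlapped, so their order at equal length was not resolved. Among the other factors, Nanog overlapped 30.6% of Smad3 peaks (28.1 to 33.2), against 13.9% for Hdac1, 6.53% for Tgif1 and 3.51% for Tgif2. Each of these shares exceeded rotation (one-sided permutation p = 0.001, the smallest possible here). Ranking by tag number raised the Tgif1 shares to 38.3% for Hdac1, 14.2% for Nanog and 12.6% for Smad3, and that for Tgif2 to 55.1%. The same ranking gave 45.5% of Smad3 peaks with Nanog, 23.7% with Hdac1, 13.3% with Tgif1 and 9.62% with Tgif2.

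Stronger Tgif1 peaks coincided with the other factors more often. In 5 bins of 3280 Tgif1 peaks each, ordered by fold enrichment, the share with Tgif2 rose from 70.5% (68.9 to 72.1) in the weakest bin to 87.5% (86.3 to 88.6) in the strongest. The share with Hdac1 rose from 53.8% to 73.7%, that with Nanog from 27.4% to 41.6% and that with Smad3 from 2.74% to 7.20%. Each series rose at every step. Under ranking by tag number the difference between the strongest and the weakest bin changed from 17.0 to 36.6 percentage points for Tgif2. The median Tgif1 peak narrowed from 1027 bp to 866.5 bp with rising fold.

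**Figure D2:**
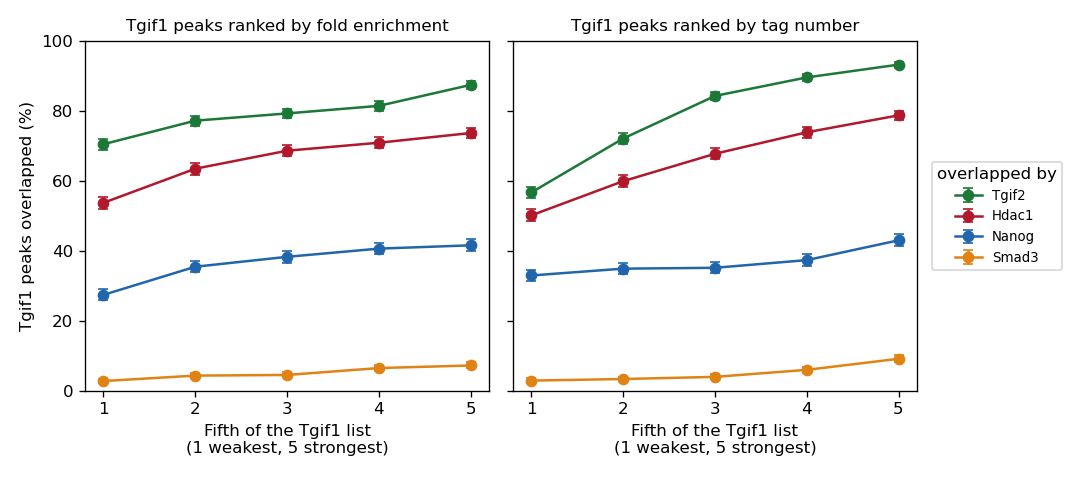
Share of Tgif1 peaks (vertical axis, %) overlapped by Tgif2, Hdac1, Nanog or Smad3 in 5 equal bins of the Tgif1 list, from weakest (1) to strongest (5), ranked by fold enrichment (left) and by tag number (right), with 95% Wilson intervals. The lines rise in both panels, for Tgif2 from 70.5% to 87.5% by fold and from 56.7% to 93.3% by tags.

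In the Nanog list ranked by fold, overlap rose most for Smad3, by 18.7 percentage points between the weakest and the strongest bin, against 11.6 for Hdac1. By tag number Smad3 rose least in points, by 24.9 against 48.5 for Hdac1. It started far lower, going from 0.405% to 25.3%, against 26.3% to 74.8% for Hdac1. Relative to the weakest bin, Smad3 overlap rose most under both rankings. Smad3 peaks overlapped 0.869% (0.609 to 1.24) of Nanog peaks in the weakest bin by fold and 19.5% (18.2 to 20.9) in the strongest. Tgif1 overlapped 41.3% of Nanog peaks in the weakest bin, 29.2% in the fourth and 41.9% in the strongest, so that share did not rise steadily, although by tag number it rose from 21.7% to 60%. In the Hdac1 list, Nanog overlap rose from 30.4% to 60.4%, while Tgif1 overlap fell from 67.9% (66.3 to 69.5) to 61.0% (59.3 to 62.6). That last direction depended on the ranking, since by tag number Tgif1 overlap of Hdac1 peaks rose from 36.9% to 89.2%. Tgif2 overlap of Hdac1 peaks turned in the same way, from 73.7% to 64.4% by fold and from 41.0% to 90.4% by tags. The median Hdac1 peak narrowed from 1201 to 908 bp with rising fold and widened from 783 to 1679.5 bp with rising tags. The part of peak width in these directions was not tested.

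Where peaks were shared, the summits lay close together. The median distance from a Tgif1 summit to the nearest Tgif2 summit was 41 bp (95% interval 40 to 42). It was 48.5 bp (45 to 54) to Smad3, 59 bp (56 to 61) to Nanog and 65 bp (62 to 67) to Hdac1. Tgif2 summits lay within 50 bp of the Tgif1 summit in 56.3% of shared peaks, Smad3 in 51.3%, Nanog in 45.1% and Hdac1 in 43.3%. Placing each Tgif1 summit at random inside its peak gave mean medians of 258 bp to Hdac1, 231 bp to Nanog and 233 bp to Smad3, and medians from 243 to 258 bp to Tgif2. Each observed median was shorter (one-sided permutation p = 0.001, the smallest 1000 placements can give). With peak midpoints in place of summits the medians were 84 bp for Tgif2, 90 bp for Smad3, 99 bp for Hdac1 and 109 bp for Nanog. Random placement gave 252, 235, 262 and 234 bp for these, also longer in each case (one-sided permutation p = 0.001). Random placement therefore cannot tell closeness of summits from overlap of peaks with nearby centres. For each factor the summit median was still shorter than the midpoint median.

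Among the other pairs, Smad3 and Nanog overlapped most completely. Nanog peaks overlapped 1107 of the 1226 Smad3 peaks, or 90.3% (88.5 to 91.8), which was 91.6 times the chance level. Hdac1 overlapped 81.1% of Smad3 peaks (78.8 to 83.2), Tgif1 67.5% (64.9 to 70.1) and Tgif2 63.7% (61.0 to 66.3). Smad3 and Nanog summits lay a median of 35 bp apart (32 to 38), against 179 bp after random placement, a comparison with the same limit as above. In the opposite direction Smad3 overlapped 6.43% of Nanog peaks (6.08 to 6.81). Nanog peaks coincided with Hdac1 in 45.9% (45.1 to 46.6), with Tgif2 in 36.7% (36.0 to 37.5) and with Tgif1 in 35.8% (35.1 to 36.5). Hdac1 peaks coincided with Tgif2 in 68.4% (67.6 to 69.1), with Tgif1 in 64.6% (63.8 to 65.3) and with Nanog in 45.6% (44.9 to 46.4). Tgif2 peaks coincided with Tgif1 in 68.0% (67.3 to 68.6), with Hdac1 in 59.9% (59.2 to 60.6) and with Nanog in 32.2% (31.5 to 32.9).

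All 20 ordered pairs exceeded rotation, each with a one-sided permutation p = 0.001 and the same value after adjustment over the 20 pairs. Restricting each list to peaks at or above its median fold lowered several shares by more than 1.5 times. This setting left 8636 of 17272 Nanog and 9568 of 19129 Tgif2 peaks, and shorter lists alone can lower these shares. Tgif2 overlap fell to 39.6% of Smad3 peaks and 20.3% of Nanog peaks, Tgif1 overlap to 22.5% of Nanog peaks, and Nanog overlap to 18.2% of Tgif2 peaks and 23.4% of Tgif1 peaks. Smad3 overlap fell to 2.52% of Tgif2 peaks.

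Merging overlapping peaks of the 5 lists gave 33152 regions. Nanog alone occupied 7483 regions, the most frequent class, and Tgif1 with Tgif2 and Hdac1 occupied 4907, the next. Tgif1, Tgif2, Hdac1 and Nanog without Smad3 shared 3384 regions, and Tgif1 with Tgif2 alone shared 2831. Tgif1 alone held 1493 regions, compared with 3425 for Tgif2 alone, 1850 for Hdac1 alone and 78 for Smad3 alone. All 5 factors shared 665 regions, 2.01% of the total. Rotating every list gave a mean of 8.20 regions with Tgif1, Tgif2 and Hdac1, a mean of 0.211 with these and Nanog, and none with all 5 factors in 1000 rotations. Rotation gave a mean of 15657 regions with Tgif1 alone and 16608 with Nanog alone, far above the observed numbers. With peaks at or above the median fold of each list the 5-factor class held 178 regions, the class of 4 without Smad3 held 788, and Tgif1, Tgif2 and Hdac1 held 1910. Joining peaks by summits within 200 bp left 3429 regions with Tgif1 alone.

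**Figure D3:**
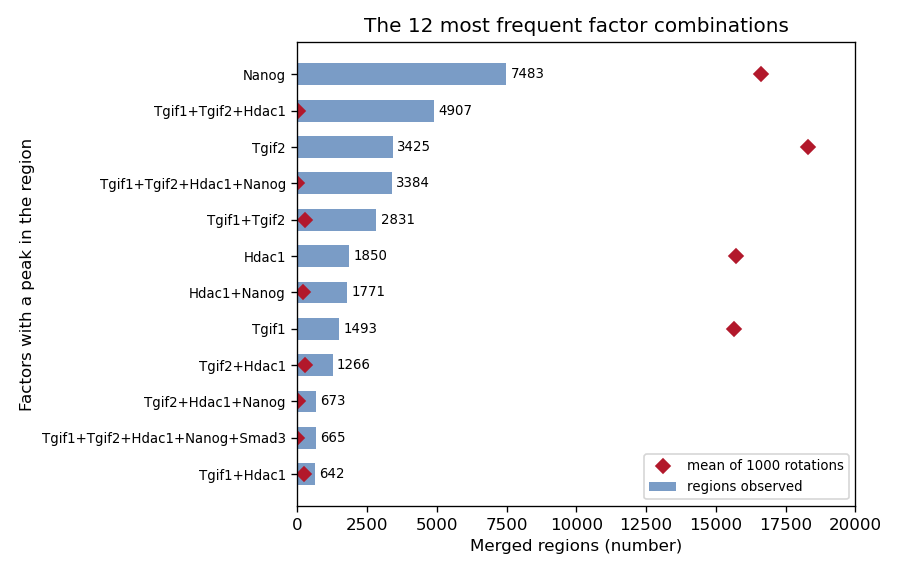
Number of merged regions (horizontal axis) for the 12 most frequent combinations of factors (vertical axis), observed (bars with their numbers) and as the mean of 1000 rotations of all lists (diamonds). Nanog alone leads with 7483 regions, and the 4907 regions with Tgif1, Tgif2 and Hdac1 stand against a chance mean of 8.20.

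Tgif1 occupancy of Nanog regions differed with the presence of Hdac1. Of 7926 Nanog peaks with an Hdac1 peak, 63.4% (62.3 to 64.5) also carried Tgif1. Of 9346 Nanog peaks without Hdac1, 12.3% carried Tgif1, giving an odds ratio of 12.3 (95% interval 11.4 to 13.3). With Tgif2 in the place of Tgif1 the shares were 63.3% (62.3 to 64.4) and 14.2% (13.5 to 14.9), with an odds ratio of 10.4 (9.69 to 11.3). The p of Fisher's exact test lay below the smallest number the software can hold, and describes these lists only. Across the 5 bins of Nanog fold the odds ratio for Tgif1 ran from 7.81 (6.68 to 9.14) in the weakest to 18.9 (15.5 to 23.2) in the fourth, and was 15.5 (12.8 to 18.9) in the strongest. The odds ratio was not split by Nanog tag number or peak width. By tag number, overlap of Nanog peaks rose from 21.7% to 60% for Tgif1 and from 26.3% to 74.8% for Hdac1. Peak strength by tags was therefore not separated from the presence of Hdac1.

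The 10 strongest Tgif1 peaks, ranked by fold enrichment, were shared with Tgif2 more often than with Nanog. Of the 10 strongest, 10 overlapped Tgif2, 8 Hdac1, 1 Nanog and 0 Smad3. The highest, in mm9 coordinates, was chr11:31770563-31771416 with a 289-fold enrichment and 283 tags, followed by chr2:30400237-30401380 with 288-fold and 284 tags. Both overlapped Tgif2 and Hdac1 and neither overlapped Nanog or Smad3. The next were chr11:5640174-5641673 (158-fold), which alone among the 10 overlapped Nanog, chr4:109348684-109349832 (156-fold) and chr2:165065074-165065566 (154-fold, no Hdac1). The remaining 5 were chr13:53472371-53473093, chr7:31319514-31320938, chr6:31256880-31257440 (no Hdac1), chr3:104565071-104565701 and chr9:106558252-106558886, with enrichments from 143-fold down to 123-fold. By tag number the 10 leading Tgif1 peaks overlapped Nanog in 6 and Smad3 in 3 cases, so the number of leading peaks with Nanog depended on the ranking. The cases with Smad3 included chr15:74915880-74917530 and chr18:40467635-40468050, places that also ranked 1 and 2 by tags in the Smad3 list. Nor did the 10 leading peaks by fold stand for strong Tgif1 peaks at large. Nanog overlapped 41.6% of the 3280 Tgif1 peaks in the strongest bin by fold, against 36.7% of all Tgif1 peaks.

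Of the 3 strongest Tgif2 peaks, 2 overlapped the leading pair of Tgif1 peaks. The strongest, chr2:30400212-30401444, reached 569-fold and chr11:31770435-31771451 reached 361-fold. The Tgif2 peak that followed, chr10:116233216-116233821 at 288-fold, overlapped no other factor. The strongest Hdac1 peaks were chr8:14072280-14073161 (199-fold), chr18:25826464-25827173 (188-fold) and chr19:4988831-4989641 (142-fold), each with Tgif1 and Tgif2 and without Nanog. The strongest Nanog peak, chr17:84750295-84752803 at 844-fold, carried Tgif1, Hdac1 and Smad3 but not Tgif2. Those that followed, chr12:100537883-100538798 (631-fold) and chr2:33435369-33438040 (598-fold), carried Tgif1, Tgif2 and Hdac1. The strongest Smad3 peak, chr13:105275310-105275936 at 37.5-fold, overlapped no other factor, while chr12:87842429-87843450 (35.7-fold) and chr3:34656703-34657255 (35.3-fold) overlapped all 4. By tag number, the 3 leading Hdac1 peaks carried Nanog in 3 cases, against 0 by fold. The 3 leading Tgif2 peaks carried Hdac1 in 0 cases by tags and 2 by fold, and the 3 leading Nanog peaks carried Smad3 in 3 cases by tags and 1 by fold. Tgif1 was at 3 of the leading Smad3 peaks by tags and 2 by fold.

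Among the 663 Tgif1 peaks overlapped by all 4 other factors, which were 4.04% of the list, the highest Tgif1 fold was 108 at chr4:149310792-149311668. It was followed by 90.8-fold at chr15:74365563-74366812 and 90.3-fold at chr12:78065880-78066816. The last of the 5 leading places were chr6:29582381-29583154 (83.8-fold) and chr4:108662054-108663160 (83.7-fold). No gene is named for these regions, because annotation of the mm9 build was not used here.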

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

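The moves of 10 to 50 kb, the runs without chromosome 1 or without the 1% of peaks with the most tags, and the alternatives for peaks of a single Tgif paralog were chosen after the data were seen. Among the alternative values, 203 kept their direction and side of the threshold, or stayed within their limit where there was no test, and 8 did not. None of these changed direction, whereas the overlap of the Hdac1 bins with Tgif1 and Tgif2, not among them, turned with the ranking. So did that of the Nanog bins with Tgif2, which fell by 2.79 points by fold and rose by 34.1 by tags. By tag number, the strongest minus the weakest Tgif1 bin became 36.6 points for Tgif2, 28.6 for Hdac1, 10.1 for Nanog and 6.25 for Smad3. Tgif1 peaks rich in tags were also wider, at a median of 1537 bp against 683.5 bp, and the cause was not tested. At or above each list's median fold, fewer peaks left 178 regions with all 5 factors, 788 with 4 factors without Smad3 and 1910 with Tgif1, Tgif2 and Hdac1. Summits within 200 bp, a stricter match, left 3429 regions with Tgif1 alone. The share of Tgif1 peaks with Tgif2 ranged from 48.9% to 79.4%, with Hdac1 from 21.5% to 66.4%, with Nanog from 7.01% to 36.7% and with Smad3 from 3.63% to 6.36%. The lowest came from lists of equal length, except for Smad3, where peaks at or above the median fold gave it. All of these shares counted as kept, because chance lay far below each of them. The count of 203 therefore does not speak to the size of the shares. The share of Smad3 peaks with Nanog was 80.6% without the 1% of peaks with the most tags and 30.6% with lists of equal length. Moves of 10 to 50 kb set a higher chance level, 5.92% for Tgif2, 5.39% for Hdac1, 3.68% for Nanog and 0.344% for Smad3, and each observed share stayed above it. Not run for lack of such a column was the limit of 1% on the false discovery rate. Alternatives that need mm9 annotation or sequence were not run either. No paired analysis was possible because each factor had 1 library. The minimum tag number of each list limits the peaks called absent from it.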

Other observations

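The comparisons of peaks of a single Tgif paralog, the further splits of the lists, the clusters and the chromosome comparisons were chosen after the data were seen. The 5 tests of explanations were written down before their values were seen, but after the patterns themselves, including the medians of each chromosome, were known.

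Peaks of a single Tgif paralog differed in their partners. The 3408 Tgif1 peaks without Tgif2 coincided with Nanog in 35.3% (33.7 to 36.9), close to the 37.0% (36.2 to 37.9) of the 12992 Tgif1 peaks with Tgif2. The 6126 Tgif2 peaks without Tgif1 coincided with Nanog in 21.9% (20.9 to 23.0). The odds ratio of Tgif1-only over Tgif2-only peaks was 1.95 (1.77 to 2.14) for Nanog, 3.34 (2.46 to 4.57) for Smad3 and 1.47 (1.35 to 1.60) for Hdac1. Hdac1 coincided with 43.6% of Tgif1-only, 34.5% of Tgif2-only and 72.0% of common peaks. Alternatives gave 1.68 to 2.32 for Nanog, 2.40 to 3.71 for Smad3 and 1.45 to 1.79 for Hdac1. Tgif1-only peaks had a median of 40 tags against 59 for those with Tgif2, near the list minimum of 30, and Tgif2-only peaks 44 against 67, near the minimum of 33, so peaks of either set could hold the other paralog below the minimum of its list.

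Hdac1 and Nanog related to Tgif1 unequally. Hdac1 peaks with Nanog carried Tgif1 in 64.5% (63.4 to 65.6) and those without Nanog in 64.7% (63.7 to 65.6), an odds ratio of 0.992 (0.930 to 1.06). This split did not hold Hdac1 peak strength equal. From the weakest to the strongest Hdac1 bin, Nanog overlap rose while Tgif1 overlap fell by fold, and both rose by tags. Opposite trends could therefore cancel in this odds ratio. Hdac1 peaks with Tgif2 carried Tgif1 in 81.7% and those without in 27.6%, an odds ratio of 11.7 (10.9 to 12.7). Nanog peaks with Smad3 carried Hdac1 in 87.2% (85.1 to 89.1) and those without in 43.0% (42.3 to 43.8), an odds ratio of 9.03 (7.54 to 10.9). The same split gave 73.2% and 33.2% for Tgif1, an odds ratio of 5.49 (4.78 to 6.32). Tgif1 peaks with Hdac1 carried Tgif2 in 86.3% and those without in 65.4%. For Nanog the same split of Tgif1 peaks gave 45.3% and 19.8%, an odds ratio of 3.36 (3.12 to 3.63). None of these splits held peak strength equal. By tags, Smad3 overlap rose from 0.405% to 25.3% between the weakest and strongest Nanog bins. Hdac1 overlap rose from 26.3% to 74.8% there, and Tgif1 overlap from 21.7% to 60%. By fold, Tgif1 stood at 41.3% and 41.9% in these bins. In the Hdac1 bins, Tgif1 and Tgif2 overlap both rose by tags and both fell by fold. These odds ratios were therefore not separated from peak strength.

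Peaks of each factor were grouped along the chromosomes. Joining peaks up to 12.5 kb apart put 27.9% of Tgif1 peaks in 1089 groups of at least 3, against 2.68% after uniform placement. The shares were 29.8% for Tgif2, 26.3% for Hdac1, 27.4% for Nanog and 5.30% for Smad3, against 3.42%, 2.69%, 2.35% and 0.0122%. The X chromosome held 0.671% of Tgif1, 0.659% of Tgif2 and 0.576% of Hdac1 peaks, but 1.71% of Nanog and 1.88% of Smad3 peaks.

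The overlap of Tgif1 with Tgif2, obtained per the labels with an antibody for one and streptavidin beads for the other, was set against 2 other sources of common peaks. Grouping of peaks in the same neighbourhoods of 10 to 50 kb was argued against as the whole source. Moving each Tgif2 peak by that distance left 5.91% of Tgif1 peaks overlapped (5.39 to 6.58 over 1000 moves), against 79.2% as observed. Narrow peaks overlap little after such a move in any case, so only the gap to the observed share counts. Grouping within less than 10 kb was not tested by these moves. Places with a called peak in every list were argued against as the whole source. Tgif2 overlapped 66.4% (65.0 to 67.8) of the 4450 Tgif1 peaks without a called Hdac1, Nanog or Smad3 peak. This share was 12.5 times the value after such moves. A place below the minimum of 28 tags for Hdac1, 16 for Nanog or 11 for Smad3 counted as absent there. Places common to all libraries with signal under these minima stay open. Binding of both paralogs at common sites is therefore a hypothesis that these lists leave standing. Open and untested here are an antibody that recognises both paralogs, open chromatin that enters any list, and a control library common to the lists.

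Chromosome 1 peaks had higher median tags than those of the other autosomes in all 5 lists and lower median fold, which for Smad3 was not resolved, at 8.93 (8.15 to 9.47) against 9.63 (9.38 to 9.86). The median Tgif1 peak held 62 tags (60 to 65) on chromosome 1 and 54 (53 to 54) on the other autosomes, with fold at 11.4 (10.9 to 11.7) and 13.5 (13.3 to 13.6), and chromosome 1 ranked first of 19 autosomes for tags and last for fold in each list. A single stretch was argued against in the Tgif1, Tgif2 and Hdac1 lists, where at least 9 of 10 segments lay above the other autosomes. For Smad3 9 segments did, but a segment there held as few as 2 peaks. For Nanog only 7 did. A single stretch therefore stays open for Smad3 and Nanog. Stronger binding and more copies of chromosome 1 in part of the cells both stay open, because chromosome 1's part of the 5% with the highest fold (at most 0.567 times its share of peaks for Tgif1, Tgif2 and Hdac1, 0.744 for Nanog, and 1.53 for Smad3 among only 61 peaks) and of the 5% with the most tags (at least 1.62 times for Tgif1, Tgif2 and Hdac1) largely restate the pattern, and mapping or background effects were not tested. At summits common to both lists, Tgif2 tags relative to Tgif1 tags were higher on chromosome 1 by 0.20 (0.15 to 0.23) on the log2 scale than on the other autosomes together, whose single values ran from -0.07 to 0.05, and relative to Hdac1 tags by 0.15 (0.07 to 0.21), while Hdac1 relative to Tgif1 stood at 0.03 (-0.01 to 0.09), inside the range of the other autosomes (-0.10 to 0.06).

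The Tgif1 peak chr18:40467635-40468050, singled out after its values were seen, overlapped all 4 other lists and ranked 2 by tags for Tgif1, 5 for Tgif2, 1 for Hdac1, 1 for Nanog and 2 for Smad3, at fold percentiles from 17.5 to 85.8. The Tgif1 peak chr15:74915880-74917530 ranked 1 by tags in the Tgif1, Tgif2 and Smad3 lists with 2391, 1758 and 1141 tags, at fold percentiles of 79.1, 60.3 and 1.22. Whether the tags at these places reflect binding or background was not tested.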
